A study of Arabidopsis thaliana with 8 samples.

How the data were processed

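Leaf RNA of 2 lines of Arabidopsis thaliana, M6PR and Col, with and without 100 mM NaCl was measured on 8 Affymetrix ATH1-type arrays, 2 biological replicate pots for each line and salt level. Per the labels' protocols, plants grew in 10 h of light and 14 h of dark at 23 and 18 °C. NaCl was given from day 14 and raised by 50 mM every 2 days. Leaves of at least 15 seedlings were pooled at 20 days. Total RNA was extracted with a column kit and labelled with biotin.

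The deposited values are log2 intensities, 1 per probe set and array, for 22810 probe sets. The submitters' processing notes name GCOS and RMA without versions. The background model, and whether arrays of the other series that shares the Col arrays entered the normalization, are not stated. The deposited log2 values have a shared lowest value of 2.15, and 27.8% to 29.2% of the probe sets lie within 0.01 of it on each array, with array medians from 5.03 to 5.32. Values near that floor cannot show a decrease. A background level of log2 4 was chosen after the values were seen. Where the dimmer group lies below it, a fold is given as a lower bound against it, and none is given where both groups lie below it.

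Groups were taken from the sample titles. The 64 array controls were left out, and 22746 probe sets were tested. Gene names come from the table of the array's probe sets: 13513 probe sets had 1 gene, 503 had several and 8730 had none. Of the first, 13436 were matched to a gene of the RefSeq annotation TAIR10.1, which served for names only. A gene on several probe sets was represented by the one with the highest mean over all arrays.

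One linear model per probe set with a mean for each of the 4 groups was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes variances (residual degrees of freedom 4, prior 0.409). The 7 contrasts were salt in Col, salt in M6PR, genotype at 0 mM, genotype at 100 mM, the interaction, and the average genotype and salt effects. Probe sets with a two-sided Benjamini-Hochberg adjusted p under 0.05 are called higher or lower. The prior was 1.11 without the 4695 probe sets within 0.01 of the floor on all arrays and 1.02 without the 4534 of almost no variance. The 23 gene lists held 485 genes, of which 68 had a probe set of their own. The 12 lists with at least 3 measured genes were tested with camera at its preset correlation of 0.01, adjusted over the lists of each contrast, and again with an estimated correlation. Groups of at least 8 genes with a common symbol prefix were tested in the same way. The r of genotype and salt changes was set against 100 simulated sets of unchanged groups.

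The comparisons, tests, lists and alternatives were fixed before the data were examined, and so was the rule for named genes. It takes the 8 largest rises and falls past the threshold of each pairwise contrast (4 for the others) among probe sets of 1 gene, filled with the smallest p where fewer pass, up to 3 called members per direction of each list, and 14 genes fixed in advance. Of those 14, PDF1.2 had a probe set of its own, and the rest (RD29A, RD29B, RAB18, NCED3, P5CS1, SOS1, HKT1, NHX1, PR1, VSP2, CHS, AT2G21250 and AT2G21260) were not analysed here.

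The fit was tested on simulated data for the 4 pairwise contrasts, with the real means and spreads of 22746 probe sets, of which 67, 67 and 66 were changed by 1, 2 and 4 log2 units. For salt in Col, 10.4%, 37.3% and 77.3% of these were called, with 3 false calls among 86. For salt in M6PR the shares were 19.4%, 43.3% and 86.4%, with 10 false among 109. For genotype at 0 mM they were 10.4%, 37.3% and 75.8%, with 1 false among 83. For genotype at 100 mM they were 23.9%, 56.7% and 74.2%, with 38 false among 141. Over 20 further simulations 26.3% of the calls for genotype at 100 mM were false with the groups' own spreads and 7.13% with an equal spread in all groups, against 12.2% and 6.94% for salt in M6PR, 8.93% and 7.03% for salt in Col and 1.66% and 7.31% for genotype at 0 mM. A shifted list of 10 genes was called in each contrast and 0 of 11 unshifted lists were. The simulated genes varied independently, so this does not test the preset correlation on lists of correlated genes.

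Alternatives were dropping the dimmest 25% of probe sets, a further quantile normalization, centring on array medians, variances with a trend and robust prior, replicate numbers as a block, only the arrays of the 2 compared groups, a minimum change of 2-fold, other list tests, and leaving out each array. Added after the data were seen were leaving out 2 doubted arrays together and pairing the salted arrays in either order. A pseudocount does not apply to log2 values.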

Results

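Leaf transcripts of Arabidopsis thaliana were measured on 8 Affymetrix arrays, 2 for each of 4 groups: Col wild type without added salt (Col 0 mM), Col with 100 mM NaCl (Col 100 mM), the transgenic line M6PR without salt (M6PR 0 mM) and M6PR with 100 mM NaCl (M6PR 100 mM). M6PR plants carry mannose-6-phosphate reductase of celery, an enzyme of mannitol synthesis, and the series title calls them mannitol-producing and salt-tolerant. Each array holds RNA from leaves of at least 15 seedlings of a replicate pot, taken 20 days after sowing and 6 days after salt began. The number of arrays limits the precision, and all group values below are means of 2 arrays with SD or SE. A log2 change that starts or ends below a background level of log2 4 is not a measured size. The rule for named genes still picked them by it, and many are listed in that order. For such genes the order is no ranking of true sizes, and folds are lower bounds. The transgene's own level was not analysed here, so it gives no check of the genotype labels. The descriptions of the 4 M6PR samples name the accession Ws, while the wild type is Col. If that holds, differences between the accessions are confounded with the transgene in every comparison of the lines. The labels say that the 4 Col arrays are also part of another series, so a batch difference shared by the Col arrays is confounded with the genotype difference at each salt level and in their average.

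The first principal component placed Col 0 mM at one end (−75.8 and −74.0) and Col 100 mM at the other (82.0 and 53.8). The M6PR arrays lay between them, at −7.59 and 13.1 without salt and at −30.0 and 38.4 with salt. This component held 48.7% of the variance and the second 31.3%. Replicates of Col 0 mM differed least (root mean square SD 0.198 on the log2 scale), followed by M6PR 0 mM (0.287), Col 100 mM (0.466) and M6PR 100 mM (0.492). The array labelled M6PR 100 mM replicate 1 correlated most closely with M6PR 0 mM replicate 1 (r 0.983 across probe sets), then with its own replicate (0.982) and with the Col 0 mM arrays (0.981 with each). Of 384 probe sets that separated salted from unsalted plants by more than 1 log2 unit on the other 7 arrays, 13.0% lay on the salted side on this array. Of 911 such probe sets found without either M6PR 100 mM array, 7.57% lay on the salted side on replicate 1 and 62.6% on replicate 2. Salt comparisons within M6PR therefore compare the arrays so labelled, and values without this array are given beside the results it moves.

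**Figure D1:**
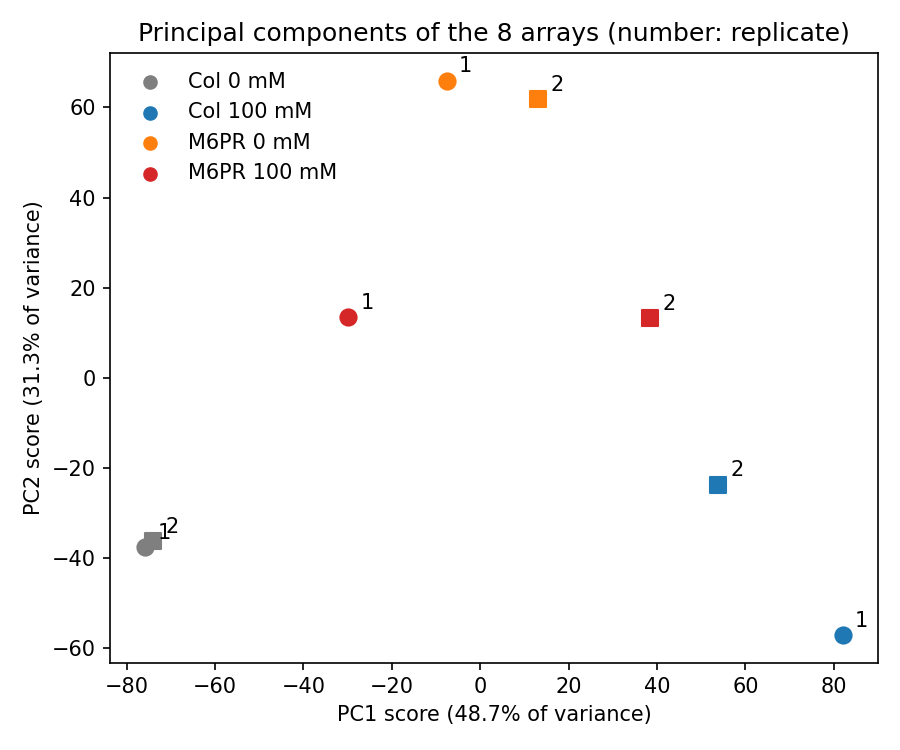
Scores of the 8 arrays on the first and second principal components of the log2 values, coloured by group, with the replicate number beside each point. Both Col 0 mM arrays lie together near −75.8 and −74.0 on the first component, and the 2 M6PR 100 mM arrays lie apart at −30.0 and 38.4.

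Salt in the wild type, Col 100 mM against Col 0 mM, changed 1193 of 22746 probe sets (limma, adjusted p under 0.05), 512 higher and 681 lower with salt. The direction of most calls depended on the processing. After each array was centred on its median, which moved the median change of all probe sets to −0.22, 1388 were higher and 2866 lower, and among changes of at least 2-fold 408 were higher and 340 lower. The count was 597 without Col 0 mM replicate 1, 816 without Col 0 mM replicate 2, 828 without Col 100 mM replicate 1 and 1939 without Col 100 mM replicate 2, and without either of the last 2 arrays most calls were higher (548 and 1069). AT3G02480, a small protein of the late embryogenesis abundant family, rose from 2.50 to 10.45 (log2 change 7.96, SE 0.57, adjusted p 0.0118), at least 87.5-fold above the background level. AT4G29780 rose by 7.35 (at least 128-fold), the expansin-like gene EXLA1 by 6.82, AT3G15630 by 6.75, AT4G29030 by 6.39, AT2G25735 by 6.34 and AT3G10930 by 6.26, each from below the background level. STZ, a zinc finger transcription factor, rose from 4.87 to 11.52, or 100.4-fold (SE 0.44). The dehydrin gene LTI30 rose by 5.64, XTH19 by 4.42, and WRKY53 by 3.49, and SPCH from below the background level to 4.21 (at least 1.16-fold). AT1G20070 (−4.14) and AT2G40230 (−3.28, 9.73-fold) fell and stayed above the background level. AT5G42760 (−4.33, at least 9.25-fold), AT1G79160 (−3.28, at least 7.98-fold), GIS (−3.36, at least 6.15-fold), AT2G21560 (−3.85), AT5G11460 (−3.24) and TINY2 (−3.47) fell to below it. LHCB4.3, of the light-harvesting antenna, fell by 1.73, thylakoid ascorbate peroxidase TAPX by 0.96 and the sorbitol dehydrogenase gene AT5G51970 by 0.98. The calls of 8 of the 23 (AT5G11460, AT3G02480, EXLA1, AT3G15630, STZ, AT3G10930, TAPX and WRKY53) passed without any one of the 4 arrays. The other 15 lost their call without at least 1 array: 15 genes without Col 0 mM replicate 1, 13 without Col 0 mM replicate 2, 11 without Col 100 mM replicate 1 and 6 without Col 100 mM replicate 2, with adjusted p up to 0.197. With only the 4 Col arrays in the fit 11 of the 23 calls were lost, AT3G10930 (adjusted p 0.0520) and TAPX among them. TAPX also lost its call without both doubted arrays, Col 100 mM replicate 1 and M6PR 100 mM replicate 1 (0.0776).

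A total of 5 fixed gene lists passed the list test for salt in Col with the preset correlation, and none of them did with an estimated correlation. Dehydration and ABA-responsive genes were higher (6 measured, median change 2.72, adjusted p 0.000370, 0.386 with the estimated correlation), with 2 members called over all probe sets and 3 adjusted over the list alone. Photosynthesis genes were lower (5 measured, median −0.32, adjusted p 0.00476, estimated 0.386), with 1 member called and 4 adjusted over the list alone. Cell wall loosening genes were higher (10 measured, median 1.89, adjusted p 0.0152, estimated 0.386), with 2 called higher over all probe sets, and 7 higher and 2 lower adjusted over the list alone. This list no longer passed without Col 100 mM replicate 2 (adjusted p 0.0988). Flavonoid and anthocyanin genes were lower (5 measured, median −2.23, adjusted p 0.0190, estimated 0.390), with 0 members called (6210 of all 22746 probe sets had an unadjusted limma p under 0.05) and 4 adjusted over the list alone. Their test missed the threshold without any one of the 4 arrays, with adjusted p of 0.0614 and 0.0712 without Col 0 mM replicates 1 and 2, and 0.0614 and 0.0653 without Col 100 mM replicates 1 and 2. Senescence genes were higher (3 measured, median 1.61, adjusted p 0.0415, estimated 0.390), with 1 called and 2 adjusted over the list alone. They missed the threshold without Col 0 mM replicate 1 (0.0716), Col 0 mM replicate 2 (0.0712) or Col 100 mM replicate 2 (0.414).

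Salt in M6PR changed 39 probe sets, 2 higher and 37 lower, and 2405 had an unadjusted p under 0.05. Centring on array medians gave 46 higher and 198 lower. Leaving out either replicate of M6PR 100 mM turned the majority from lower to higher, with 140 calls (105 higher, 35 lower) without replicate 1 and 829 (535 higher, 294 lower) without replicate 2. Without M6PR 0 mM replicate 1 there were 191 calls and without replicate 2 there were 388. AT1G51790 (4.91-fold), AT5G25440 (−2.23, 4.69-fold), the cell cycle inhibitor gene SIM (−1.72), AT5G39020 (−1.69) and AT2G23200 (−1.51) fell and stayed above the background level. AT5G62865 fell from 6.16 to below it (−2.66, SE 0.13, adjusted p 0.0275, at least 4.47-fold), and AT3G54150 (−1.97) and AT3G03000 (−2.03) fell from 4.39 and 4.33 to below it. AT2G16800 was the only named rise past the threshold (0.73, adjusted p 0.0415). Below the threshold, the changes were 3.54 for the wax ester synthase gene WSD1 (adjusted p 0.0752, from the floor), 0.70 for AT1G06760 (0.0689) and 0.31 for AT3G59630 (0.0532), and AT1G63850, AT5G63820, AT5G45310 and MPC also missed it (0.0618, 0.0517, 0.0740 and 0.0752). The calls of AT5G39020, AT3G54150, AT3G03000 and AT5G62865 held without any one of the 4 arrays. All 9 named calls were lost with only the M6PR arrays in the fit, these 4 with adjusted p of 0.196, 0.228, 0.105 and 0.157, where limma called 0 probe sets (1975 at an unadjusted p under 0.05). AT3G54150 and AT5G62865 also lost their calls without both doubted arrays. The other 5 of 9 called genes lost their call without at least 1 array, 4 without M6PR 0 mM replicate 1, 3 without M6PR 0 mM replicate 2 and 4 without M6PR 100 mM replicate 1, with adjusted p up to 0.101.

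In the list tests for salt in M6PR, dehydration genes were again higher (median 1.65, adjusted p 0.000574, 0.546 with the estimated correlation), with 0 members called over all probe sets (2405 probe sets had an unadjusted limma p under 0.05) and 3 adjusted over the list alone. The change of AT3G02480 was 5.26 (adjusted p 0.0813), from below the background level. This list missed the threshold without M6PR 100 mM replicate 2 (0.0544). Flavonoid genes moved up in M6PR (median 1.42, adjusted p 0.00369, estimated 0.546), with 0 called and 2 adjusted over the list alone. They missed the threshold without M6PR 0 mM replicate 2 (0.138) or without M6PR 100 mM replicate 1 (0.118).

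Across all probe sets the salt responses of the 2 lines, which share no array, had a Pearson r of 0.0617 and a Spearman rho of 0.113. Probe sets are not independent replicates. The r became 0.448 without M6PR 100 mM replicate 1, −0.299 without M6PR 100 mM replicate 2 and −0.0622 without M6PR 0 mM replicate 1, so its sign rests on single arrays. Of the probe sets called in both, 5 fell in both lines, 5 moved in opposite directions and 0 rose in both, with 2 rises called in M6PR to share.

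Without salt, M6PR differed from Col in 1599 probe sets, 904 higher and 695 lower in M6PR, of which 1173 differed at least 2-fold. The count fell to 533 without M6PR 0 mM replicate 1, 885 without M6PR 0 mM replicate 2, 748 without Col 0 mM replicate 1 and 998 without Col 0 mM replicate 2. Without either Col 0 mM array most calls were lower in M6PR (469 and 674). AT3G15630 was 12.09 in M6PR against 2.51 in Col (9.58, SE 0.39, adjusted p 0.00379), at least 272-fold. EXLA1 was 9.06 higher (11.94 against 2.87, adjusted p 0.00595), at least 245-fold. EXO was 7.50 higher (181-fold), AT3G15450 7.09 higher (136-fold), and AT1G50040 (7.49), AT3G59350 (7.39), AT4G16563 (6.80) and AT2G25735 (6.80) rose from below the background level. STZ was 4.84 higher in M6PR (28.6-fold), EXLA2 4.76 and SAG101 1.31. The anthocyanin glucosyltransferase gene AT4G14090 (UGT75C1) was 10.45 in Col and 4.16 in M6PR (−6.29, SE 0.76, 78.2-fold, adjusted p 0.0226), and UF3GT was 10.79 and 5.53 (−5.26, 38.3-fold, adjusted p 0.0214). AT5G01790 (−4.86, 29.0-fold) and AT1G20070 (−4.77, 27.3-fold) were also lower in M6PR. AT1G60590 (−5.78, at least 46.2-fold), AT2G15020 (−5.93, at least 28.9-fold), AT1G48100 (−4.94, at least 26.2-fold) and AT2G44940 (−5.06, at least 23.2-fold) were lower and below the background level in M6PR. Of the expansin genes EXPA4 was lower (−2.35), as was EXPA15 (−2.22, at least 3.46-fold). AT3G15630 and EXLA1 passed without any one of the 4 arrays. The other 19 lost their call without at least 1 array, 17 without M6PR 0 mM replicate 1, 13 without M6PR 0 mM replicate 2, 17 without Col 0 mM replicate 1 and 15 without Col 0 mM replicate 2, with adjusted p up to 0.186. With only the 4 arrays at 0 mM in the fit 6 of the 21 calls were lost (adjusted p up to 0.106).

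Flavonoid and anthocyanin genes were the list that passed for M6PR against Col without salt (median −4.61, adjusted p 0.000719, 0.910 with the estimated correlation). Of its 5 measured genes 2 were called over all probe sets and 5 adjusted over the list alone, namely AT4G14090, UF3GT, 5MAT (−4.61), UGT78D2 (−3.53) and DFR (−1.78). The list passed without any one of the 4 arrays. Cell wall loosening genes went both ways, with 2 called higher and 2 lower, and the list did not pass (adjusted p 0.442).

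**Figure D2:**
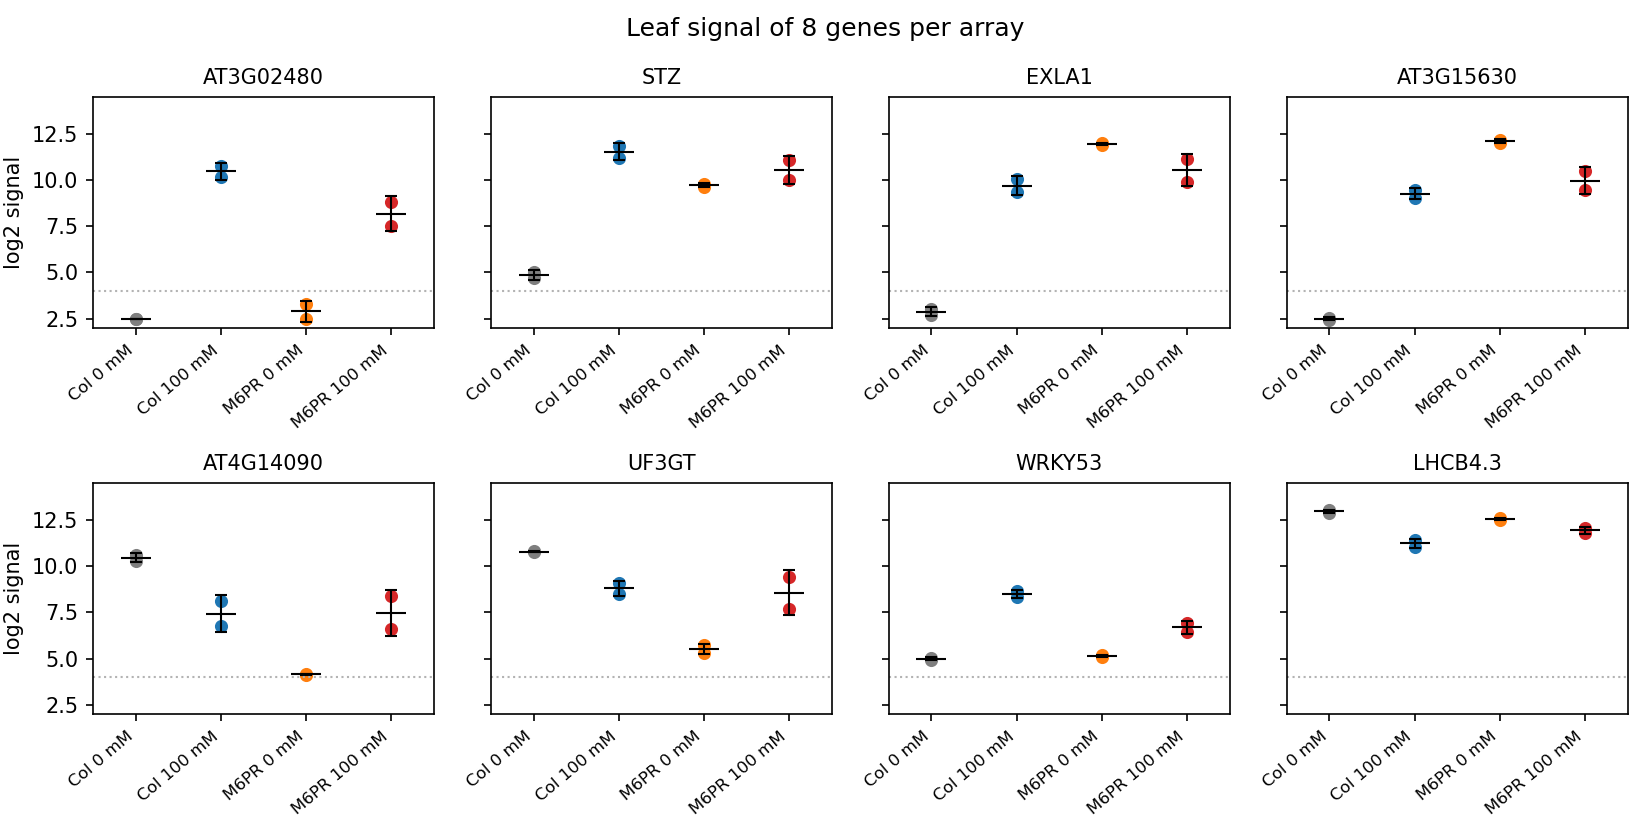
The log2 signal of 8 genes on each array by group, 2 points per group, with the group mean as a wide bar and the SD as error bars, and the background level of 4 as a dotted line. EXLA1 and AT3G15630 lie below that line on both Col 0 mM arrays and above 9 on the other 6 arrays, while AT4G14090 and UF3GT are highest in Col 0 mM and lowest in M6PR 0 mM.

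The difference between M6PR and Col without salt resembled the change that salt brought in Col. Across probe sets the Pearson r was 0.588 and Spearman's rho 0.466. Both contrasts subtract the same Col 0 mM arrays, and simulated unchanged groups sharing such arrays gave an r of 0.501. The simulation gave a probe set the same spread in all groups, while real Col 0 mM replicates differed least (root mean square SD 0.198). That r is therefore not a matched reference. The covariance was 0.475 observed against 0.0549 simulated. The simulation holds noise only, so it cannot separate a resemblance from a shift of the shared Col 0 mM arrays, which would also raise the covariance. Of the called probe sets, 264 were higher in both, 291 lower in both and 18 opposite, and the shared arrays add to this overlap. EXLA1, AT3G15630, STZ and AT2G25735 are among the shared rises and AT1G20070 among the shared falls. The r ranged from 0.508 to 0.634 when single arrays were left out.

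With 100 mM NaCl, M6PR differed from Col in 31 probe sets, 8 higher and 23 lower, of which 23 had a mean signal below the background level, and 2947 had an unadjusted p under 0.05. In simulated arrays with the groups' real spreads, 38 of 141 calls of this comparison were false. After centring on array medians, which moved the median difference of all probe sets to 0.20, 77 were higher and 62 lower. The count was 107 without M6PR 100 mM replicate 1, 1014 without M6PR 100 mM replicate 2, 366 without Col 100 mM replicate 1 and 1212 without Col 100 mM replicate 2, with 79 and 680 higher, the majority, without the M6PR arrays. UGT76E12 (6.65 in Col, 2.42 in M6PR, −4.24, adjusted p 0.0229) and AT5G33370 (−3.98, adjusted p 0.0172) were lower and below the background level in M6PR, as was AT1G17830 (−2.38). BUB3.2, AT1G16480, AT3G42860, AT5G01075 and AT4G20320 were called lower, and AT3G45840 and AT3G42910 higher, with both groups below the background level. AT1G78450 was higher in M6PR by 2.75 (adjusted p 0.0205; below the background level in Col), AT3G19850 by 2.22 and AT5G37710 by 1.91. Without M6PR 100 mM replicate 1 these 3 rises missed the threshold (adjusted p 0.0641, 0.0654 and 0.0756), as did AT1G16480 and AT5G01075 (0.0823 and 0.0967). With only the 4 salted arrays in the fit all 13 named calls were lost (adjusted p from 0.0895 to 0.484), and limma called 0 probe sets (1375 at an unadjusted p under 0.05). GT2 was 1.58 higher but did not pass (adjusted p 0.0519), nor did AT5G63820 and AT2G06570 (0.0580 each). Photosynthesis genes were higher in M6PR in the list test (median 0.14, adjusted p 0.0351, 0.511 with the estimated correlation), with 0 called over all probe sets (2947 had an unadjusted limma p under 0.05) and 1 adjusted over the list alone. That test missed the threshold without any one of the 4 arrays (0.191 and 0.138 without M6PR 100 mM replicates 1 and 2, 0.0554 and 0.0816 without Col 100 mM replicates 1 and 2).

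The salt response itself differed between the lines in 330 probe sets (interaction test), with 118 responding more positively in M6PR and 212 less, and 2234 without M6PR 100 mM replicate 2. Centring gave 470 and 552. The count was 1130 without Col 100 mM replicate 2, 572 without Col 0 mM replicate 2 and 501 without Col 100 mM replicate 1. Most responded more positively in M6PR without M6PR 100 mM replicate 2 (1321), Col 0 mM replicate 1 (330 of 446) or Col 0 mM replicate 2 (450). The response of AT3G15630 was 8.88 log2 units lower in M6PR (−8.88, SE 0.54, adjusted p 0.0148): it rose in Col and went from 12.09 to 9.95 in M6PR. Values were also negative for EXLA1 (−8.24), AT2G25735 (−7.12), AT3G15450 (−6.53) and STZ (−5.82). AT3G15630, EXLA1 and AT2G25735 read below the background level in Col 0 mM, so their values are not measured sizes. TINY2 (3.77), AT5G11460 (3.13), AT3G15310 (3.01) and AT3G51330 (2.99) fell with salt in Col from levels of 5.16 to 6.02 and lay below the background level in M6PR with and without salt. Flavonoid genes responded more positively in M6PR (median 4.31, adjusted p 0.00307, 0.439 with the estimated correlation), with 0 called over all probe sets (4161 had an unadjusted limma p under 0.05) and 4 adjusted over the list alone. AT3G15630 and AT3G15310 passed without any single array, but AT3G15310 did not without both doubted arrays. Neither passed with replicate numbers as a block (limma adjusted p 0.0598 for AT3G15630). The other 7 of the 9 named genes lost their call without at least 1 array, 7 without M6PR 0 mM replicate 1, 6 without M6PR 0 mM replicate 2, 5 without each of the 4 Col arrays and 1 without M6PR 100 mM replicate 1, with adjusted p up to 0.144.

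**Figure D3:**
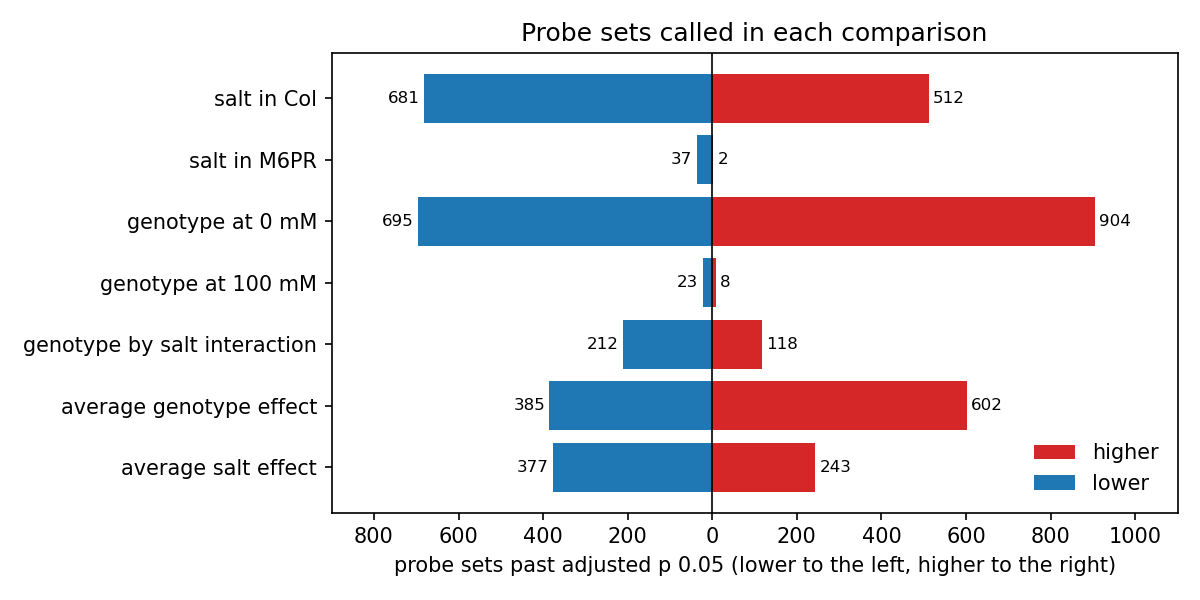
Number of probe sets past an adjusted p of 0.05 in each of 7 comparisons, lower to the left in blue and higher to the right in red. The comparisons that use the Col 0 mM arrays hold the most calls, with 904 higher and 695 lower between the lines without salt, against 8 and 23 with salt.

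Averaged over salt levels, M6PR differed from Col in 987 probe sets, 602 higher and 385 lower. The count was 412 without M6PR 0 mM replicate 1, 626 without Col 0 mM replicate 1, 1509 without M6PR 100 mM replicate 2 and 1877 without Col 100 mM replicate 2. Most were lower in M6PR without Col 0 mM replicate 1 (398) or 2 (556 of 819), or Col 100 mM replicate 1 (503 of 855) or 2 (1066). AT1G50040 (5.38), AT4G16563 (5.23), AT3G15630 (5.13) and EXLA1 (4.94) were higher, and AT5G41400 (−3.08), AT1G60590 (−3.01), AT5G62210 (−2.91) and the endoglucanase gene GH9C2 (−2.69) lower, as were EXPA15 (−2.14), EXPA4 (−1.29) and SPCH (−0.93, below the background level in 3 groups). For AT3G15630 and EXLA1 the average is mostly the gap without salt, where Col read below the background level. With salt AT3G15630 read 9.427 and 10.471 in M6PR and 9.47 and 9.045 in Col. EXLA1 read 9.902 and 11.123 against 9.339 and 10.039. AT1G60590 (−5.78 without salt) and EXPA4 (−2.35) also owe most of their average to the gap without salt. The flavonoid list had a median of −4.61 without salt and 0.05 with salt. Flavonoid genes were lower (median −2.45, adjusted p 0.00767, estimated 0.896), with 0 called over all probe sets (4162 had an unadjusted limma p under 0.05) and 4 adjusted over the list alone, and missed the threshold without Col 0 mM replicate 2 (0.0598) or Col 100 mM replicate 2 (0.136). AT5G62210, AT5G41400, AT3G15630 and EXLA1 passed without any single array, though AT5G62210 did not without both doubted arrays (adjusted p 0.0786). The other 7 of 11 named genes lost their call without at least 1, with adjusted p up to 0.138: 7 without each of the 4 arrays at 0 mM, 4 without Col 100 mM replicate 1, 2 without Col 100 mM replicate 2 and 2 without M6PR 100 mM replicate 1.

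Averaged over the lines, salt changed 620 probe sets, 243 higher and 377 lower, while changes of at least 2-fold were 145 higher and 98 lower. The count was 311 without M6PR 0 mM replicate 1, 1673 and 1072 without M6PR 100 mM replicates 1 and 2, and 1623 without Col 100 mM replicate 2. Most rose with salt without any one of the salted arrays (856 and 666 without M6PR 100 mM replicates 1 and 2, 446 of 741 and 882 without Col 100 mM replicates 1 and 2). AT3G02480 (6.61), the transcription factor gene ORA47 (4.50), AT2G37870 (4.22), AT4G29780 (4.03), LTI30 (3.79), STZ (3.74), LEA4-5 (2.82), EXLA1 (2.69), WRKY53 (2.51) and SPCH (1.09) rose on average. For EXLA1 this is the rise in Col, since in M6PR it read 11.90 and 11.97 without salt and 9.90 and 11.12 with salt. For STZ it is mostly the rise in Col, since in M6PR it read 9.63 and 9.78 without salt and 10.00 and 11.07 with salt. The average of AT4G29780 also came mostly from Col, where it rose by 7.35. SPCH read above the background level in Col 100 mM only. AT3G46880 (−2.68), AT3G16530 (−2.30), AT1G51790 (−2.00), AT3G16670 (−1.95), LHCB4.3 (−1.18) and TAPX (−0.71) fell. Dehydration genes were higher (median 2.197, adjusted p 3.53e-05, estimated 0.320; 3 called, 5 adjusted over the list alone) and photosynthesis genes lower (median −0.17, adjusted p 0.00376, estimated 0.320; 1 called, 3 adjusted over the list alone). Senescence genes were higher (median 1.70, adjusted p 0.0135, estimated 0.320; 1 called and 1 adjusted over the list alone), but not without M6PR 100 mM replicate 1 (0.0627) or Col 100 mM replicate 2 (0.0738). Cell wall loosening genes were higher (median 0.62, adjusted p 0.0135, estimated 0.320, 1 called and 4 adjusted over the list alone). They did not pass without M6PR 100 mM replicate 2 or Col 100 mM replicate 2. Their average rise came from Col (median 1.89), since in M6PR the median was −0.38 and the list test did not pass (adjusted p 0.424). AT1G51790, AT3G46880, AT3G02480, AT2G37870 and WRKY53 passed without any single array. The other 11 of 16 named genes lost their call without at least 1, with adjusted p up to 0.151: 10 and 9 without M6PR 0 mM replicates 1 and 2, 10 and 9 without Col 0 mM replicates 1 and 2, 5 and 4 without Col 100 mM replicates 1 and 2, and 1 without M6PR 100 mM replicate 2.

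Genes for mannose, mannitol and polyol metabolism, the pathway of the transgene, did not pass as a list in any of the 7 comparisons (8 measured, medians from −0.09 to 0.11, adjusted p from 0.432 to 0.978). Nor did compatible solute genes (3 measured, adjusted p from 0.510), reactive oxygen scavenging genes (6 measured, from 0.0660), glucosinolate and camalexin genes (3 measured, from 0.121), heat shock protein genes (4 measured, from 0.172), root markers (3 measured, from 0.290) or markers of guard cells and epidermis (3 measured, from 0.172). Among 84 list tests 15 passed, and the sign of the test, the median and the mean differed in 12 tests, 0 of them among those 15. Of 31 groups of genes that share a symbol prefix, each tested in 7 comparisons, 1 test passed, for NET genes in M6PR against Col with salt (10 measured, median −0.33, adjusted p 0.0296, 0.779 with the estimated correlation), with 0 of them called (limma; 2947 of all probe sets had an unadjusted p under 0.05). PDF1.2, a defensin gene fixed in advance, read 11.22 in Col 0 mM and 6.53 in Col 100 mM, with 10.39 (SD 2.92) and 8.70 (SD 2.41) in M6PR, and did not pass in any comparison (salt in Col, −4.69, adjusted p 0.194).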

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

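All tests in this part except the interaction test were chosen after the results were seen, and what each explanation predicts was set after its value was known.

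The response to salt differed between the lines in 330 probe sets by the interaction test. Among the named genes, the response in M6PR minus that in Col was −8.88 for AT3G15630, −8.24 for EXLA1, −7.12 for AT2G25735, −6.53 for AT3G15450 and −5.82 for STZ, and 3.77 for TINY2, 3.13 for AT5G11460, 3.01 for AT3G15310 and 2.99 for AT3G51330. The median over the flavonoid and anthocyanin list was 4.31. AT3G15630, EXLA1, AT2G25735, AT3G15450 and STZ were already high in M6PR without salt, and the 4 genes with positive values read below the background level in M6PR with and without salt.

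The lines differed in 1599 probe sets without salt and in 31 with salt, where replicates also lay further apart. A difference common to all 4 Col arrays, such as their use in another series, would leave the same gap at both salt levels. Over the 1599 probe sets called without salt, the median ratio of the gap with salt to the gap without was 0.0733 (quartiles −0.0878 and 0.286). By single pairs of salted arrays it was 0 and 0.0203 with M6PR 100 mM replicate 1, and 0.124 and 0.142 with replicate 2. These probe sets were picked by their gap without salt, which by itself lowers the ratio. Ratios this low still argue against a difference common to the Col arrays as the whole cause of this pattern. A stress or handling signal that the Col 0 mM plants alone lacked may account for part of it: a list of 20 rapid stress and touch genes was at least 2.29 higher on each of the other 6 arrays than in Col 0 mM (1.62 without 4 genes already named). That signal cannot be told apart from an effect of the transgene without salt, because only the Col 0 mM group lacks it. The same holds for a difference of accession, if the M6PR plants are Ws as described. A batch that affected the Col 0 mM arrays alone stays open too.

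The array labelled M6PR 100 mM replicate 1 lay nearest to M6PR 0 mM replicate 1 (r 0.983), and about as near to the Col 0 mM arrays (0.981) as to its own replicate (0.982). Col RNA on this array is argued against by the probe set that separates the lines by the widest gap on the other 7 arrays, which read 8.66 to 9.09 on the Col arrays and 2.77 on this one, though only 57.7% of 149 probe sets that separate the lines lay on the M6PR side (43.2% on Col 100 mM replicate 2). An unsalted plant under a wrong label stays open. Only 13.0% of the 384 probe sets that separate the other salted and unsalted arrays lay on the salted side. The probe set with the widest gap among them (6.11) read 2.42 here, on the unsalted side. Against that, the dehydration list lay 1.33 above its unsalted mean, beyond the highest unsalted array (0.71). AT3G02480 (7.49, at most 3.30 unsalted) and ORA47 (9.61, at most 6.01) went with the label. These 2 genes were picked because they separate all 8 arrays by label, this array included, so they do not test it. A different moment or manner of harvest may also play a part, as the rapid stress list was lower than in replicate 2 (−0.92, against differences of 0.02 to 0.11 in size in the other groups), and a pot that responded less to salt was not tested. These cannot be told apart with 1 array. Replicate deviations of the 2 M6PR groups also correlated (0.486), and a cause shared by the M6PR replicates was not tested. Of 657 salt-separating probe sets found without this array and M6PR 0 mM replicate 2, 12.6% lay on the salted side here and 23.1% on that unsalted array. The poly-A spikes of this array were the highest and its hybridization spikes the lowest of all arrays (7.15 and 7.53), and a technical cause was not tested.

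On Col 100 mM replicate 1, 69 plastid-encoded transcripts had a median 1.68 below replicate 2 (−1.68), lower in 62 of 69. The 25S rRNA control read 2.34 against at least 7.08 elsewhere. Of the controls of RNA quality, the 3′ actin control exceeded the 5′ one by 1.79 against 0.81 to 1.14 elsewhere. The same difference for GAPDH was 0.128, about that of M6PR 100 mM replicate 1 (0.127), so it does not set this array apart. A dim array is argued against by the hybridization spikes, which read 8.29, within the 7.53 to 8.99 of the other arrays. Less RNA without a poly-A tail in the preparation may account for it, since the nuclear photosynthesis list differed by −0.04. It cannot account for the poly-A spikes, which carry tails and read 2.25 on this array against 3.90 to 7.15 on the others. RNA breakdown stays open, since the actin and GAPDH controls differ on it, and no biological explanation was tested.

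In data outside the comparisons, the poly-A spikes read 7.15 on M6PR 100 mM replicate 1, above both Col 0 mM arrays (5.65 and 5.29).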

How the results depend on the processing

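Leaving out both doubted arrays (Col 100 mM replicate 1 and M6PR 100 mM replicate 1) and pairing the salted arrays in either order were chosen after the results were seen, and the other alternatives before the data were examined.

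The cause of the changes below was not tested unless stated. No named gene result and no list median past the threshold changed direction under any alternative run, while PDF1.2, which did not pass, changed sign for salt in M6PR (−3.75 to 0.37), genotype at 0 mM (−2.89 to 1.23) and the average genotype effect (−0.36 to 1.70). Dropping the dimmest probe sets moved the count to 3491 for salt in Col, 116 for salt in M6PR, 70 for genotype at 100 mM, 1025 for the interaction, 1669 for the average genotype effect and 1460 for the average salt effect. Centring on medians gave 4254, 244, 139, 1022, 1638 and 2080 for the same 6. The count for genotype at 0 mM stayed within 1.5 times of 1599 under both. With the replicate block the 7 counts were 497 for salt in Col, 13 for salt in M6PR, 970 for genotype at 0 mM, 3 for genotype at 100 mM, 53 for the interaction, 415 and 210 for the average genotype and salt effects. Replicate deviations of different groups correlated from −0.151 to 0.0826 except between the M6PR groups (0.486).

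With only the arrays of the 2 groups, limma called 792 for salt in Col, 0 for salt in M6PR (1975 at an unadjusted p under 0.05) and 0 for genotype at 100 mM (1375). With the 4 salted arrays alone, a block of crossed numbers gave 0 (2548 at an unadjusted p under 0.05) and a replicate block of equal numbers 0 (1248). A minimum of 2-fold left 748 for salt in Col, 24 for salt in M6PR, 16 for genotype at 100 mM, and 512 and 243 for the average genotype and salt effects. Without both doubted arrays the counts were 1814, 435, 587, 900 and 1894 for salt in Col, salt in M6PR, genotype at 100 mM, the interaction and the average salt effect, and the r of the 2 salt responses was 0.422. Of the 1814, 542 were among the original calls, and 1123 were higher.

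Leaving out each array in turn, where the lone array of a group is assumed to vary like the others, gave 597 to 1939 for salt in Col, 140 to 829 for salt in M6PR, 533 to 998 for genotype at 0 mM, 107 to 1212 for genotype at 100 mM, 248 to 2234 for the interaction, 412 to 1877 for the average genotype effect and 311 to 1673 for the average salt effect. The number of list tests past the threshold was 9 (without Col 100 mM replicate 2) to 15. The r of the salt responses ranged from −0.299 (without M6PR 100 mM replicate 2) to 0.448 (without M6PR 100 mM replicate 1) and was −0.0622 without M6PR 0 mM replicate 1. The r of genotype and salt changes ranged from 0.508 to 0.634, and its Spearman rho was 0.466. With an estimated correlation camera passed 0 lists of 84 where the preset passed 15, and fry passed 18, of which 10 were among those 15.

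Of 119 named gene results, 102 past the threshold, the quantile normalization ended 11 calls and gained 3, the trend 10 and 1, the dim filter 7 and 3, centring 7 and 5, the replicate block 59 and 0, only the arrays of the 2 groups 39 and 1 (pairwise contrasts only), and leaving out both doubted arrays 28 and 3. Signal over background limits falls: 4695 probe sets are within 0.01 of the floor on all 8 arrays.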

Other observations

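All tests and gene lists in this part were chosen after the results were seen.

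Genes known to rise within minutes to an hour of touch, wounding or cold (25 listed, 20 measured) had a higher median in the other 3 groups than in Col 0 mM. It was 3.74 higher in Col 100 mM and 2.96 higher in M6PR 0 mM than in Col 0 mM, with 17 and 14 of the 20 called higher, and the median change with salt in M6PR was −0.04. ORA47 was an exception, at 5.96 in Col 0 mM and 5.04 in M6PR 0 mM, AT5G57510 read below the background level in all groups, and CML37 in all but Col 100 mM (4.23). Without AT4G29780, AT2G25735, AT3G10930 and ORA47, which were already named, the medians were 2.99 and 2.71, with 13 and 11 of 16 called higher. The list test on these 16 gave an adjusted p over 3 lists of 5.88e-15 for salt in Col (0.0441 with an estimated correlation) and 7.28e-15 for genotype at 0 mM (0.0445). AT1G25400 rose from 2.79 in Col 0 mM to 8.71 in M6PR 0 mM and 8.14 in Col 100 mM, and AT1G76600 from 6.03 to 10.92 and 11.59.

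Genes known to rise in darkness or when sugar is short (41 listed, 16 measured) were higher in M6PR than in Col without salt, with a median difference of 2.29, 12 called higher and 0 lower. Without AT3G15630 and AT3G15450, which were already named, the median was 2.00 and 10 of 14 were called higher (list test adjusted p 6.15e-13, 0.0130 with an estimated correlation). AT5G19120 read 5.96 in Col 0 mM, 12.47 in M6PR 0 mM, 11.26 in Col 100 mM and 12.10 in M6PR 100 mM. The kinase subunit gene AKINBETA1 was 3.31 higher in M6PR 0 mM than in Col 0 mM, AT4G27450 4.58 and MCCA 2.03. The median change with salt of the 14 list genes not named before was −0.54 in M6PR (adjusted p 1.77e-05, 0.0660 with an estimated correlation), with 0 called where 2405 probe sets had an unadjusted limma p under 0.05. It was 1.06 in Col (5.96e-06, 0.0441 with an estimated correlation), with 5 called higher and 1 lower. The 4 groups were harvested from separate pots, and the labels give no time of day.

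Plastid-encoded transcripts (69 measured of 125) had 0 calls in any comparison (limma, 4472 of all probe sets at an unadjusted p under 0.05 for genotype at 0 mM), with a median of −0.55 for salt in Col (adjusted p 0.00581, 0.602 with an estimated correlation), but against Col 0 mM it was −1.45 on Col 100 mM replicate 1 and 0.17 on replicate 2, so the direction turned without replicate 1. For salt in M6PR the median was −0.34, with 2 of 69 above 0 (adjusted p 0.00118, 0.765 with an estimated correlation).

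Few probe sets kept a difference between the lines on all arrays. All 4 M6PR arrays lay more than 2 log2 units from all 4 Col arrays in 5 probe sets, against 10 for salt and at most 6 in the other splits of the 8 arrays. AT4G16563, AT5G25240, AT1G11380 and 1 probe set without a gene name were higher in M6PR. Another probe set without a gene name was lower, at 2.77 to 3.86 in M6PR and 8.66 to 9.09 in Col.

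The 8 arrays were also split 4 against 4 in other ways, in the model used for the averages, with a mean for each side at each level of the other factor. The split by line called 987 probe sets, 1 of 34 splits (itself) called as many and the highest other called 862. Many of the 34, that of 862 among them, divide the arrays of a salt level unevenly, unlike the split by line. Even exchanges within each salt level are too few to reach 0.05. Chance could therefore not be excluded for the average genotype effect in this form. The split by salt called 620, 6 of 34 splits called as many and the highest other called 1241, so chance could not be excluded for the average salt effect. That highest split set both Col 0 mM arrays, M6PR 0 mM replicate 1 and M6PR 100 mM replicate 1 against the rest. Within Col it is the split by salt, and within M6PR it goes by replicate number. Its count therefore does not by itself show a structure apart from the labels. Of the 6 splits, those with 629, 794, 802 and 1046 calls divide the arrays of a line unevenly, unlike the split by salt. This form replaced a first one with 1 mean per side, which leaves the other factor in the residual, and in which 5 of 35 splits called as many as the line split (1 call) and 3 as many as the salt split (2 calls).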
